A study of Homo sapiens with 28 samples.

How the data were processed

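RNA of 28 subcutaneous xenograft tumours of 2 human renal cell carcinoma lines had been measured on 1-colour Affymetrix HG-U133 Plus 2.0 arrays, after extraction with Trizol from snap-frozen tissue and biotin labelling. The values are intensity values: deposited linear probe set signals, scaled by the authors so that the trimmed mean of every array is the same. The submitters' processing notes name RMA and MAS5 without saying which step each was used for, and without a version in the sources used here. The values have the form MAS5 scaling gives: they were linear, from 0.0875 to 64034.6, with equal 2% trimmed means and unequal quantiles between arrays. Detection calls were not used here. For arrays the number of tumours, 4 or 5 per group, limits the precision.

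Groups were taken from the labels: 786-O untreated and resistant tumours of the sorafenib and of the sunitinib arm, and A498 untreated and resistant tumours. Replicate numbers only follow the order of deposition and pair no tumours, so no paired analysis was made. Values were used as log2(signal + 16). Of 54675 probe sets, 62 control probe sets were kept for the check of RNA quality only. Of the others 41091 had 1 gene symbol, 1801 several and 11721 no entry in the annotation; 41037 were matched by Entrez ID and 54 by symbol alone. A gene was represented by its probe set of highest mean among those with 1 symbol. Genes were kept when above the median of all values (signal 89.4, log2 6.72) on at least 4 arrays, which left 13808 of 19775 genes and left out 5967.

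A linear model with 1 coefficient per group was fitted over all 28 arrays with limma 3.58.1 in R 4.3.3, so that all groups share 1 estimate of the spread, with no covariate. Contrasts were resistant against untreated in each of the 3 arms, the mean of both 786-O arms, the difference between the 786-O arms, the difference between the lines under sorafenib, untreated A498 against untreated 786-O of the sunitinib arm, and untreated 786-O tumours of the sorafenib against the sunitinib arm. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 30 gene lists, among them markers of other cell types, were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. The agreement of contrasts was measured by Pearson and Spearman correlation across genes. The 3-prime minus 5-prime differences of the GAPDH and ACTB control probe sets were compared by two-sided exact permutation. Counts were set against those of 100 splits of the same arrays. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

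Design, lists, alternatives and the genes to be named were fixed before the data were examined. The rule for named genes took the 10 largest rises and 10 largest falls of a contrast among called genes without overlap between the groups (5 and 5 for the differences between arms and for untreated 786-O tumours). To these it added up to 3 called members of each called list, 13 genes named in advance, and the 5 largest in each direction called in all 3 arms. Uncharacterised loci and Y-linked genes were not named. Alternatives were pseudocounts of 1 and 64, no filter and a stricter filter at the 75th percentile, the mean of a gene's probe sets, leaving out probe sets open to cross-hybridisation, centring on the median, quantile normalisation, array weights, a trended robust variance, GAPDH as a covariate, only the arrays of a comparison, pooled untreated tumours or no term for the arm, a threshold of 1 on the log2 scale, and leaving out each array. Added after the data were seen were ACTB as a covariate, leaving out the 2 arrays of highest ACTB difference, and exact permutation of the arrays' list means.

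The model was tested on simulated data in which 50 genes of each size were shifted. Differences of 1 on the log2 scale were recovered in 86%, 78% and 82% of cases in 786-O with sorafenib, 786-O with sunitinib and A498, and differences of 0.5 in 42%, 38% and 30%. There were 8, 7 and 10 false calls among the genes not shifted, of 13808 tested. A list of shifted genes was called and 0 other lists were. Noise was drawn independently for each gene, so this does not show how the list test behaves with correlated genes. It was also normal and of the same spread in all groups, as the model assumes. The false calls therefore do not show how gene calls behave where the spread differs between groups.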

Results

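The series profiled subcutaneous xenograft tumours of 2 human renal cell carcinoma lines, 786-O and A498, grown in immunodeficient mice. Both lines lack a working VHL tumour suppressor, so that hypoxia-inducible factors are active without hypoxia. Sorafenib, an inhibitor of VEGF and PDGF receptors and of RAF kinases, was given by gavage at 80 mg/kg, and sunitinib, an inhibitor of VEGF and PDGF receptors and KIT, at 53.6 mg/kg, 6 days a week from a tumour diameter of 12 mm. Tumours were taken at 12 mm before treatment or at the permitted limit of 20 mm, and the labels do not state which size the untreated tumours had. RNA of 28 tumours was measured on 1-colour Affymetrix HG-U133 Plus 2.0 arrays with 54675 probe sets. In 786-O there were 5 untreated and 5 resistant tumours in the sorafenib arm, and 5 untreated and 4 resistant tumours in the sunitinib arm. In A498 there were 4 untreated and 5 resistant tumours, all in a sorafenib arm. Resistant here means the tumours so labelled, which had been treated and had grown on. The series title names the question as the expression changes that accompany resistance to VEGF receptor inhibitors.

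The deposited values were linear signals scaled to the same 2% trimmed mean on every array (500.06 to 500.07), with array medians between 79.7 and 99.4. Arrays of 1 group correlated with r between 0.949 and 0.971 across probe sets, and no array was a copy of another. Differences are on the log2(signal + 16) scale, which understates the change of dim genes, and are resistant minus untreated ± standard error, with limma p-values adjusted over 13808 genes. The labels give no size or time on study per tumour, so effects of these cannot be separated from those of treatment. The labels do not state that each tumour came from its own mouse, so p-values measure the spread between these samples. The probes are human, and mouse RNA of the host can bind to some of them. RNA quality, read as the 3-prime minus 5-prime signal of the GAPDH and ACTB control probe sets, differed by -0.03 to 0.05 between resistant and untreated tumours of an arm. Two-sided exact permutation p-values were 0.214 to 0.984, where the smallest possible is 0.00794. The highest ACTB differences were 1.03 (786-O untreated, sorafenib arm, replicate 5), which stood apart from its group, and 0.674 (786-O sorafenib-resistant, replicate 4), which did not.

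In 786-O tumours that had grown on sorafenib, the largest rises were in MMP1, the interstitial collagenase, from a mean signal of 91.7 ± 51.1 to 1364 ± 709 (SD, n = 5 and 5), in SCD, the stearoyl-CoA desaturase, from 359 ± 169 to 3514 ± 1379.8, and in SCG5, a neuroendocrine chaperone (3.59 ± 0.45). The falls were led by ACSM2A, a mitochondrial acyl-CoA synthetase (-3.83 ± 0.47), and UGT2B4, a glucuronosyltransferase (-3.41 ± 0.35). ALDH8A1, an aldehyde dehydrogenase (-2.80 ± 0.36), was also among the largest falls. So was SLC17A3, an organic anion and phosphate transporter of the proximal tubule (-2.59 ± 0.43). As lists, MAPK output genes (camera adjusted p = 3.31e-14) and hypoxia genes (camera adjusted p = 1.76e-07) shifted upward. Interferon-stimulated genes shifted upward (mean 0.56, adjusted p = 3.31e-14, and adjusted p = 0.0627 with an estimated correlation), and fibroblast and pericyte markers downward (mean -0.90, adjusted p = 1.51e-05, and adjusted p = 0.0524 with an estimated correlation). In all, 825 genes rose and 1267 fell, of which 448 by at least 1 on the log2 scale, and 3917 genes had an unadjusted p under 0.05.

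The other genes with the largest rises and no overlap between the groups were ARHGAP22 (3.06 ± 0.43), SLCO4A1 (3.05 ± 0.24), TMEM158 (3.00 ± 0.21) and MFSD2A (2.86 ± 0.37). They were followed by ANGPTL4 (2.65 ± 0.33), HMGA1 (2.61 ± 0.34) and MAFF (2.49 ± 0.26). SLCO4A1 is an organic anion transporter, MFSD2A carries lysophospholipids and ANGPTL4 is a secreted lipase inhibitor. Adjusted p-values of the 10 largest rises lay between 2.01e-09 (TMEM158) and 2.04e-05 (ARHGAP22). The other falls were in ZIC1 (-2.95 ± 0.74), LRRC31 (-2.81 ± 0.34) and DEFB1 (-2.80 ± 0.54), and further LEFTY1 (-2.79 ± 0.43), CALCRL (-2.59 ± 0.21) and MMP24 (-2.57 ± 0.42), where DEFB1 is an epithelial defensin and CALCRL the calcitonin receptor-like receptor. The weakest of the 10 falls by limma was ZIC1 (adjusted p = 0.00765). MMP1, SCG5, ARHGAP22, MFSD2A and HMGA1 lay below the filter limit of 6.72 (log2) in the untreated group, and ACSM2A, UGT2B4, ZIC1, LRRC31, ALDH8A1, LEFTY1, CALCRL and MMP24 below it in the resistant group, so the size of these changes is uncertain. RSAD2 and PLAT lay below it in the untreated group and FBLN1 in the resistant group. Groups of 5 and 5 did not overlap in 12.5% of the genes tested, where chance gives 0.794%.

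Among 21 measured MAPK output genes, 14 rose and 1 fell (16 and 1 adjusted over the list alone; mean 0.88, adjusted p = 3.31e-14). The ERK phosphatase DUSP5 (1.99 ± 0.20), the AP-1 member FOSL1 (1.95 ± 0.20) and PHLDA1 (1.90 ± 0.20) were among them. Of 28 hypoxia and HIF target genes 11 rose and 1 fell (15 and 1 adjusted over the list alone; mean 0.38, adjusted p = 1.76e-07). ANGPTL4, the collagen cross-linker LOX (0.98 ± 0.22) and the chemokine receptor CXCR4 (0.97 ± 0.27) were among the rises. Matrix proteases and their inhibitors gave 9 rises and 1 fall in 18 genes (9 and 3 adjusted over the list alone; mean 0.46, adjusted p = 3.77e-04). MMP1, the plasminogen activator PLAT (2.03 ± 0.39) and the urokinase receptor PLAUR (1.41 ± 0.14) rose with them. The stress list, of integrated stress and unfolded protein response genes, gave 7 rises and 1 fall in 30 (8 and 1 adjusted over the list alone; mean 0.23, adjusted p = 1.39e-04). PPP1R15A (1.25 ± 0.17) and EDEM1 (1.05 ± 0.20) were among them. These 4 lists kept their call with an estimated correlation, at an adjusted p of 0.00167 for MAPK output, 0.0194 for hypoxia, 0.0209 for proteases and 0.0441 for the stress genes.

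The other 12 called lists did not keep it. Of 38 interferon-stimulated genes 19 rose and 0 fell (27 and 0 adjusted over the list alone; mean 0.56, adjusted p = 3.31e-14). Untreated replicate 1 stood apart low on this list, and without it the mean was 0.49 and still called (0.42 to 0.65 without any 1 array of the arm). IFITM1 (1.45 ± 0.25) and ISG20 (1.23 ± 0.18) were among them, and the list had adjusted p = 0.0627 with an estimated correlation. Beside it, macrophage markers had a mean of -0.27 (camera adjusted p = 0.970, exact permutation of array means p = 0.0159). Of 21 macrophage markers listed 11 were measured and 8 lay below the filter. Of 16 cholesterol synthesis genes 10 rose and 0 fell (11 and 0 adjusted over the list alone; mean 0.58, adjusted p = 6.45e-09, and adjusted p = 0.0768 with an estimated correlation). The sterol sensor INSIG1 (1.72 ± 0.29), ACAT2 (0.89 ± 0.19) and IDI1 (0.78 ± 0.14) were among them. MHC class I presentation gave 5 rises in 18 genes (6 and 0 adjusted over the list alone; mean 0.28, adjusted p = 1.51e-05, and adjusted p = 0.108 with an estimated correlation). HLA-E (0.67 ± 0.12) was 1 of them. Probes for HLA, IFITM, AKR1C and ACSM2 genes can bind near-identical paralogs. Fatty acid and lipid droplet genes gave 7 rises and 2 falls in 17 (8 and 2 adjusted over the list alone; mean 0.39, adjusted p = 6.09e-04, and adjusted p = 0.0524 with an estimated correlation). SCD, LPIN1 (1.23 ± 0.17) and HILPDA (0.86 ± 0.20) rose. Mesenchymal genes gave 6 rises in 21 (6 and 0 adjusted over the list alone; mean 0.24, adjusted p = 0.00450, and adjusted p = 0.238 with an estimated correlation). The hyaluronan receptor CD44 (0.78 ± 0.10) was 1 of them. Immediate early genes gave 4 rises in 16 (4 and 0 adjusted over the list alone; mean 0.28, adjusted p = 0.0259, and adjusted p = 0.278 with an estimated correlation). DUSP1 (1.04 ± 0.18) was 1 of them. Glycolysis genes gave 5 rises in 18 (5 and 0 adjusted over the list alone; mean 0.21, adjusted p = 0.0267, and adjusted p = 0.336 with an estimated correlation). The glucose transporter SLC2A3 (1.70 ± 0.19) was 1 of them.

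Fibroblast and pericyte markers, which in these tumours can come from host cells, fell in 8 of 16 genes and rose in 0 (0 and 9 adjusted over the list alone; mean -0.90, adjusted p = 1.51e-05, and adjusted p = 0.0524 with an estimated correlation). COL3A1 (-1.93 ± 0.30), COL1A2 (-1.83 ± 0.27) and FBLN1 (-1.78 ± 0.44) were among them. Endothelium markers had a mean of -0.26 beside them (exact permutation of array means p = 0.0238). Only 7 of the 20 listed were measured, and 13, CDH5, KDR and VWF among them, lay below the filter. Extracellular matrix genes, which share collagens with that list, gave 2 rises and 8 falls in 28 (2 and 8 adjusted over the list alone; mean -0.36, adjusted p = 0.0498, and adjusted p = 0.393 with an estimated correlation). The angiogenesis inhibitor THBS1 (-2.07 ± 0.20) was among the falls. Falls outnumbered rises by 8 to 0 among 20 oxidative stress and NRF2 target genes (0 and 8 adjusted over the list alone; mean -0.50, adjusted p = 0.00188, and adjusted p = 0.115 with an estimated correlation). The aldo-keto reductases AKR1C3 (-2.29 ± 0.26) and AKR1C2 (-1.86 ± 0.20) and the heme oxygenase HMOX1 (-1.70 ± 0.40) were among them. Drug transporter and metabolism genes gave 1 rise and 8 falls in 19 (1 and 8 adjusted over the list alone; mean -0.34, adjusted p = 0.0417, and adjusted p = 0.260 with an estimated correlation). ALDH1A1 (-2.13 ± 0.33) and CYP1B1 (-1.50 ± 0.24) were among them. Oxidative phosphorylation genes gave 6 small falls in 25 (0 and 7 adjusted over the list alone; mean -0.18, adjusted p = 0.00281, and adjusted p = 0.393 with an estimated correlation). SDHC (-0.53 ± 0.10) and ATP5MC1 (-0.50 ± 0.11) were among them.

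The 14 lists that did not pass the test were skeletal muscle (mean -0.81, adjusted p = 0.0526), lysosome and autophagy (0.0523), angiogenic growth factors (0.0616), p53 targets (0.334), ribosomal proteins (0.347), NF-kB (0.352), receptor tyrosine kinases and drug targets (0.564), cell cycle (0.564), endothelium (0.699), epithelial genes (0.735), BMP and TGF-beta targets (0.930), macrophage and myeloid (0.970), skin and adipose (0.970) and red blood cell (0.970). For the angiogenic, NF-kB, BMP, receptor kinase, endothelium and skin lists the median, mean and test differed in sign. Among single genes fixed in advance, EPAS1 (0.90 ± 0.11), which encodes HIF-2alpha, the cytokine IL6 (1.20 ± 0.27), the receptor kinase AXL (0.56 ± 0.17) and VEGFA (0.35 ± 0.10) rose and CDKN1A (-0.41 ± 0.13) fell, while MKI67 (0.03 ± 0.18), CXCL8 (0.56 ± 0.33), CXCL10 (0.13 ± 0.45) and MET (0.16 ± 0.10) did not pass. KDR and PDGFRB lay below the filter.

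Without the 2 arrays of high ACTB difference the count in this comparison was 1233 in place of 2092, an alternative added after the data were seen. Of the 72 genes named by rule, 68 kept their call without any 1 array, and VEGFA, CDKN1A, AXL and HK2 (0.79 ± 0.25, with another probe set significant in the opposite direction) did not, all 4 without sorafenib-resistant replicate 4 and up to an adjusted p of 0.136. The drug transporter, matrix, glycolysis and immediate early lists also lost their call without 1 array, up to an adjusted p of 0.125.

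**Figure D1:**
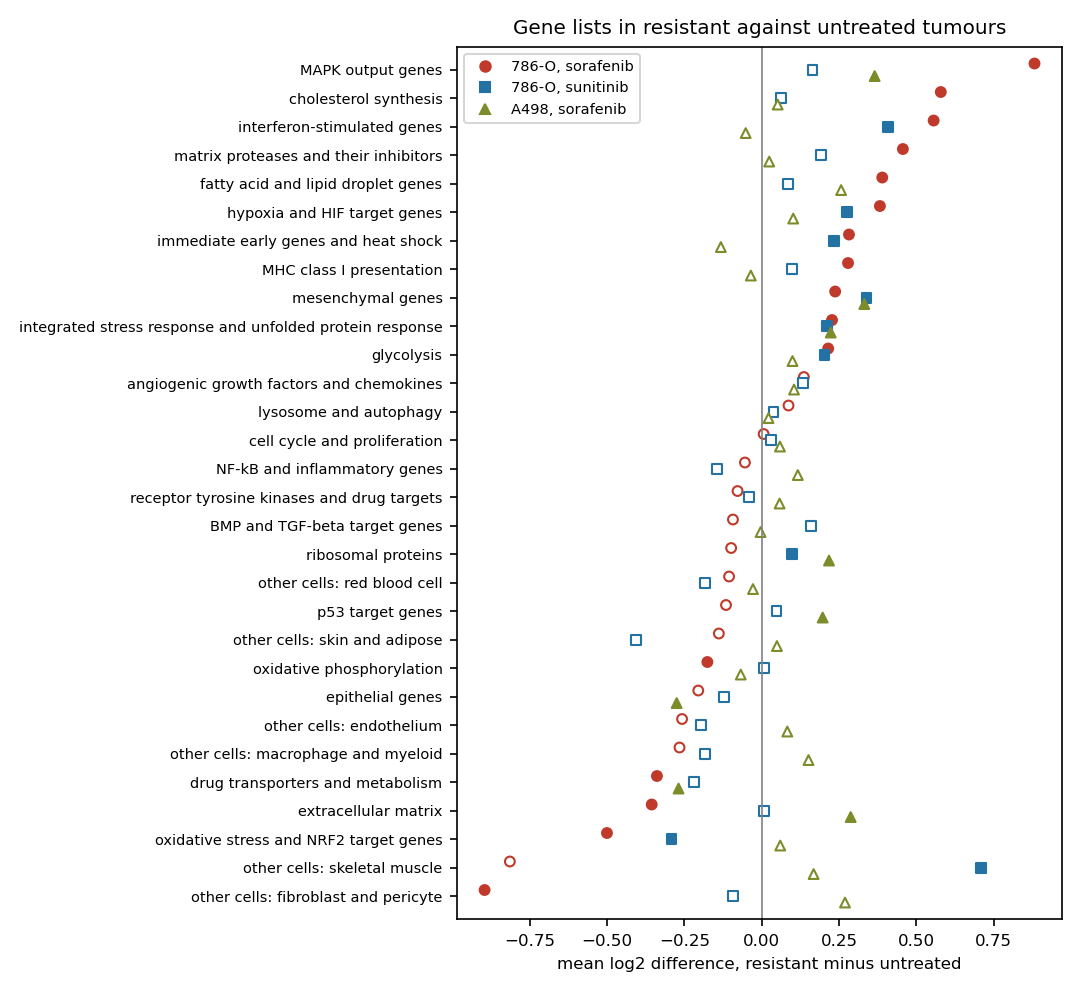
Mean log2 difference, resistant minus untreated on the log2(signal + 16) scale (horizontal axis), of each gene list (vertical axis) in 786-O with sorafenib (red circles), 786-O with sunitinib (blue squares) and A498 with sorafenib (olive triangles). Filled symbols mark lists with a camera adjusted p under 0.05 and open symbols the others: the interferon list lies at 0.56 and 0.41 in 786-O and at -0.05 in A498, and the fibroblast list at -0.90, -0.09 and 0.27.

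In 786-O tumours that had grown on sunitinib, DHRS3, a retinaldehyde reductase, rose from a mean signal of 111 ± 68.1 to 464 ± 115 (SD, n = 5 untreated and 4 resistant), and SCD from 516 ± 191 to 1730.0 ± 994. FXYD2, the regulatory subunit of the kidney Na,K-ATPase, fell from 11863 ± 2785 to 3053 ± 2048, and CLDN2, a tight junction claudin of the proximal tubule, from 943 ± 197 to 217 ± 72.7. Hypoxia genes (camera adjusted p = 3.85e-06) and stress response genes (camera adjusted p = 3.16e-05) shifted upward as lists. In all 306 genes rose and 392 fell, 155 of them by at least 1 on the log2 scale, and 2584 genes had an unadjusted p under 0.05.

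The largest rises without overlap between the groups were WFDC21P (2.48 ± 0.35), DHRS3 (2.08 ± 0.33), SHISAL1 (1.73 ± 0.30), EGFL6 (1.73 ± 0.31) and NKAIN4 (1.72 ± 0.36). Next came DLL4 (1.63 ± 0.37), SCD (1.60 ± 0.36), MYO1G (1.58 ± 0.39), TMEM158 (1.57 ± 0.22) and RNASE1 (1.55 ± 0.43). DLL4 is a Notch ligand of sprouting vessels, and with WFDC21P and RSAD2 it lay below the filter limit in untreated tumours. Adjusted p-values ran from 3.26e-04 (TMEM158) to 0.0366 (RNASE1). The largest falls were FLG (-2.77 ± 0.50), TMT1A (-2.51 ± 0.39), IRAG2 (-2.38 ± 0.39), LRRC31 (-2.19 ± 0.36) and FXYD2 (-2.13 ± 0.37). Next were PKHD1 (-2.10 ± 0.35), CLDN2 (-2.06 ± 0.32), UGT2B4 (-2.01 ± 0.37), FABP7 (-2.01 ± 0.50) and PIGR (-1.94 ± 0.42), where PKHD1 encodes fibrocystin and PIGR the polymeric immunoglobulin receptor. FLG, TMT1A, IRAG2, LRRC31, PKHD1 and AKR1B10 lay below the limit in resistant tumours, and another probe set of TMT1A was significant in the opposite direction. With a pseudocount of 1, which picks another probe set, TMT1A came out at 1.26. Groups did not overlap in 8.46% of the genes tested, where chance gives 1.59%.

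Of 28 hypoxia and HIF target genes 9 rose and 0 fell (11 and 0 adjusted over the list alone; mean 0.28, adjusted p = 3.85e-06, and adjusted p = 0.0385 with an estimated correlation). The glucose transporter SLC2A1 (0.78 ± 0.12), ANGPTL4 (1.29 ± 0.35) and LOX (0.82 ± 0.24) were among them. The stress response list gave 5 rises and 1 fall in 30 genes (11 and 1 adjusted over the list alone; mean 0.21, adjusted p = 3.16e-05, and adjusted p = 0.0385 with an estimated correlation). PPP1R15A (0.84 ± 0.18), the transcription factor DDIT3 (0.77 ± 0.20) and the mTORC1 inhibitor DDIT4 (0.44 ± 0.09) were among them. These were the only 2 of the 9 called lists to hold with an estimated correlation. Interferon-stimulated genes gave 7 rises and 0 falls in 38 (16 and 0 adjusted over the list alone; mean 0.41, adjusted p = 3.34e-09, and adjusted p = 0.261 with an estimated correlation). MX2 (1.28 ± 0.22), OAS2 (1.13 ± 0.18) and RSAD2 (1.06 ± 0.31) were among them. Mesenchymal genes gave 3 rises in 21 (3 and 0 adjusted over the list alone; mean 0.34, adjusted p = 3.86e-04, and adjusted p = 0.261 with an estimated correlation): LOX, ITGA5 (0.64 ± 0.16) and MMP2 (0.56 ± 0.16). Glycolysis genes gave 2 rises in 18 (4 and 0 adjusted over the list alone; mean 0.20, adjusted p = 6.58e-04, and adjusted p = 0.261 with an estimated correlation), SLC2A1 and PKM (0.45 ± 0.12). Oxidative stress and NRF2 target genes gave 1 rise and 5 falls in 20 (3 and 7 adjusted over the list alone; mean -0.29, adjusted p = 0.0224, and adjusted p = 0.326 with an estimated correlation). AKR1C3 (-1.54 ± 0.27), AKR1B10 (-1.41 ± 0.23) and AKR1C2 (-1.12 ± 0.22) were among them. Immediate early genes gave 1 rise in 16 (3 and 0 adjusted over the list alone; mean 0.23, adjusted p = 0.0224, and adjusted p = 0.326 with an estimated correlation), ZFP36 (0.65 ± 0.19).

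Skeletal muscle markers, which can come from host tissue next to the tumour, shifted upward as a list (mean 0.71, adjusted p = 0.0345, and adjusted p = 0.387 with an estimated correlation). Past the threshold were 0 of 6 genes, and an exact permutation of array means gave p = 0.103 (0.256 adjusted over 30 lists). Of 15 muscle genes listed 8 lay below the filter, and where the signal of the measured ones came from was not tested. Ribosomal proteins also shifted upward (mean 0.10, adjusted p = 0.0423, and adjusted p = 0.837 with an estimated correlation) with 0 of 20 genes past the threshold. Both counts held adjusted over all genes or over the list alone. The fibroblast list did not pass here (mean -0.09, adjusted p = 0.754), nor did the macrophage (0.660), endothelium (0.574) and MAPK output lists (0.0877). The 21 lists that did not pass had an adjusted p from 0.0662 to 0.918, and for the epithelial, receptor kinase, lysosome and skin lists the median, mean and test differed in sign. Of the genes fixed in advance VEGFA (0.43 ± 0.11) and EPAS1 (0.50 ± 0.12) rose, and IL6 (-0.09 ± 0.29), CXCL8 (0.00 ± 0.36), CXCL10 (0.58 ± 0.48), MKI67 (0.22 ± 0.19), CDKN1A (0.33 ± 0.14), MET (0.07 ± 0.11) and AXL (0.10 ± 0.18) did not pass.

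The count of 698 rested on single arrays more than in the sorafenib arm: it was 442 without untreated replicate 1, 313 without sunitinib-resistant replicate 3 and 396 without sunitinib-resistant replicate 4. It was 259 with only these 9 arrays in the fit and 1326 against the untreated 786-O tumours of both arms. Centring arrays on their median gave 712 calls with 55.6% of them higher, in place of 43.8%. Of the 45 called genes named by rule 18 lost their call without at least 1 array, 16 of them without resistant replicate 3, such as SCD, MYO1G, RNASE1, ANGPTL4, LOX, DDIT3, RSAD2, VEGFA and EPAS1, and DLL4 without resistant replicate 4, up to an adjusted p of 0.159. The muscle, ribosomal, NRF2 and immediate early lists lost theirs as well, up to an adjusted p of 0.496. The ribosomal mean of 0.10 was 0.01, 0.03 and 0.22 without sunitinib-resistant replicates 3, 1 and 4, and 0.05 without untreated replicate 5.

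In A498 tumours that had grown on sorafenib, SLC17A3 fell from a mean signal of 9239 ± 3777 to 1215 ± 618 (SD, n = 4 untreated and 5 resistant), HAVCR1, the kidney injury marker KIM-1, from 1259 ± 207 to 165 ± 49.1, and GLDC, the glycine decarboxylase, from 1931 ± 854 to 299 ± 151. The cell adhesion molecules NCAM1 and CADM1 rose, NCAM1 from 483 ± 111 to 1413 ± 436 and CADM1 from 1117 ± 356 to 3241 ± 794. MAPK output genes shifted upward (mean 0.37, adjusted p = 0.00289, and adjusted p = 0.484 with an estimated correlation), with the ETS factors ETV1, ETV4 and ETV5 ahead. In all 405 genes rose and 470 fell, 160 of them by at least 1 on the log2 scale, and 2893 genes had an unadjusted p under 0.05.

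The largest rises without overlap were FEZ1 (2.05 ± 0.26), BMPR1B (1.88 ± 0.39), KCNK12 (1.84 ± 0.38), TCN1 (1.83 ± 0.27) and DGKI (1.73 ± 0.44). They were followed by BCHE (1.67 ± 0.18), PTX3 (1.57 ± 0.33), CADM1 (1.54 ± 0.25), NCAM1 (1.49 ± 0.19) and IGKC (1.46 ± 0.39), with adjusted p-values from 4.32e-06 (BCHE) to 0.0240 (IGKC). TCN1 encodes a vitamin B12 binding protein and BCHE butyrylcholinesterase. FEZ1, BMPR1B, BCHE and IGKC lay below the filter limit in untreated tumours and DGKI in both groups. IGKC is an immunoglobulin light chain gene of B cells, with 4 of its 7 other probe sets in the same direction, and it lost its call, with a difference of 0.50, when probe sets open to cross-hybridisation were left out. The largest falls were CRYBB3 (-3.19 ± 0.24), SLC17A3 (-2.97 ± 0.45), HAVCR1 (-2.85 ± 0.29), GLDC (-2.68 ± 0.69) and WFDC21P (-2.05 ± 0.35). Next were ACSBG1 (-2.03 ± 0.46), UGT1A6 (-1.98 ± 0.40), CLTRN (-1.97 ± 0.33), GLYAT (-1.89 ± 0.31) and MAL2 (-1.88 ± 0.38), where CLTRN is a tubule amino acid transporter chaperone and GLYAT a glycine acyltransferase. CRYBB3, WFDC21P and UGT1A6 lay below the limit in resistant tumours, and the UGT1A genes share exons. Groups did not overlap in 9.14% of the genes tested, where chance gives 1.59%.

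Of 21 MAPK output genes 6 rose and 0 fell (8 and 1 adjusted over the list alone; mean 0.37, adjusted p = 0.00289, and adjusted p = 0.484 with an estimated correlation). ETV4 (1.74 ± 0.39), ETV1 (1.43 ± 0.32) and ETV5 (1.38 ± 0.16) were among them. The stress response list gave 4 rises in 30 genes (9 and 1 adjusted over the list alone; mean 0.22, adjusted p = 0.0187, and adjusted p = 0.484 with an estimated correlation). CHAC1 (1.21 ± 0.32), DDIT3 (1.15 ± 0.20) and the asparagine synthetase ASNS (0.65 ± 0.11) were among them. Mesenchymal genes gave 2 rises in 21 (2 and 0 adjusted over the list alone; mean 0.33, adjusted p = 0.0140, and adjusted p = 0.484 with an estimated correlation), S100A4 (2.38 ± 0.64) and CD44 (0.47 ± 0.10). Extracellular matrix genes gave 2 rises and 1 fall in 28 (5 and 2 adjusted over the list alone; mean 0.29, adjusted p = 0.0167, and adjusted p = 0.568 with an estimated correlation). COL5A1 (1.19 ± 0.34) and LAMB1 (0.76 ± 0.11) were among them. Epithelial genes gave 3 falls in 19 (1 and 4 adjusted over the list alone; mean -0.27, adjusted p = 0.0159, and adjusted p = 0.484 with an estimated correlation), CDH16 (-1.61 ± 0.33), CLDN2 (-1.29 ± 0.32) and KRT8 (-0.44 ± 0.12). Drug transporter and metabolism genes gave 1 rise and 4 falls in 19 (1 and 4 adjusted over the list alone; mean -0.27, adjusted p = 0.0194, and adjusted p = 0.484 with an estimated correlation). UGT1A6, the efflux pump ABCB1 (-1.49 ± 0.18) and SLCO2B1 (-0.99 ± 0.25) fell. CDH16 lay below the filter limit in resistant tumours, and CHAC1, ETV4 and SCG5 in untreated tumours. Target genes of p53 gave 2 rises and 1 fall in 22 (3 and 2 adjusted over the list alone; mean 0.20, adjusted p = 0.0407, and adjusted p = 0.568 with an estimated correlation). GADD45A (0.89 ± 0.24) and DDB2 (0.42 ± 0.12) were among them. Ribosomal proteins shifted upward as a list (mean 0.22, adjusted p = 0.00289, and adjusted p = 0.861 with an estimated correlation) with 0 of 20 genes past the threshold, adjusted over all genes or over the list alone. The mean was 0.11 and not called without A498 untreated replicate 3, which stood apart from its group on this list, and 0.14 without resistant replicate 2.

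None of these 8 lists held with the estimated correlation. The interferon list did not pass in A498 (mean -0.05, adjusted p = 0.241), nor did the hypoxia (0.301), fibroblast (0.242), macrophage (0.956) and endothelium lists (0.956). The 22 lists that did not pass had an adjusted p from 0.0798 to 0.956, and for the BMP, endothelium, macrophage and skin lists the median, mean and test differed in sign. IL6 (1.27 ± 0.29) rose, and VEGFA (0.30 ± 0.11), EPAS1 (0.16 ± 0.12), CXCL8 (0.42 ± 0.36), CXCL10 (-0.03 ± 0.48), MKI67 (0.04 ± 0.19), CDKN1A (0.01 ± 0.14), MET (0.20 ± 0.11) and AXL (0.43 ± 0.18) did not pass. The count of 875 was 467 without A498 untreated replicate 1, 583 without untreated replicate 4 and 571 without sorafenib-resistant replicate 3, and 185 with only these 9 arrays in the fit. Of the 46 called genes named by rule 16 lost their call without at least 1 array, 13 of them without untreated replicate 1, such as GLDC, DGKI, IGKC, S100A4, ACSBG1 and SCG5, up to an adjusted p of 0.145. The drug transporter, epithelial, matrix, stress, p53 and ribosomal lists lost theirs, up to an adjusted p of 0.155, and 5 lists were called without sorafenib-resistant replicate 3.

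Each arm had its own untreated tumours, so the 3 comparisons share no arrays. Across 13808 genes, which are not independent replicates, the sorafenib and sunitinib differences of 786-O correlated with a Pearson r of 0.41 and a Spearman coefficient of 0.33. The 786-O and A498 sorafenib differences gave 0.22 and 0.19, and 786-O with sunitinib against A498 with sorafenib gave 0.15 and 0.12. In 786-O 143 genes rose on both drugs and 216 fell on both, where independent lists would share 18.3 and 36.0, and 4 rose on sorafenib and fell on sunitinib and 4 did the reverse, where 51.5 would in all. Between the lines under sorafenib 104 genes rose in both and 151 fell in both, against 24.2 and 43.1, and 9 rose in 786-O and fell in A498 and 15 did the reverse, against 65.2.

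A set of 21 genes rose and 35 fell in all 3 comparisons, where independent lists would share 0.536 and 1.22. These numbers leave out the shared spread, and the splits did not test the overlaps. SCG5 rose by 3.59, 2.20 and 1.70 in 786-O with sorafenib, 786-O with sunitinib and A498. In the same order TMEM158, a RAS-responsive membrane protein, rose by 3.00, 1.57 and 1.10, and SHISAL1 by 1.11, 1.73 and 1.20. The kinase SIK1 rose by 1.00, 1.31 and 1.03, and MELTF, melanotransferrin, by 1.43, 1.08 and 0.98. ALDH8A1 changed by -2.80, -1.91 and -1.83, SLC17A3 by -2.59, -1.81 and -2.97. CLDN2 changed by -2.37, -2.06 and -1.29, the tetraspanin TSPAN12 by -1.47, -1.26 and -1.32. PDZK1, a scaffold of tubule transporters, changed by -2.27, -1.18 and -1.21. In A498 another probe set of MELTF was significant in the opposite direction. SCG5, MELTF, PDZK1, CLDN2 and SHISAL1 lost their A498 call without A498 untreated replicate 1, and MELTF, PDZK1 and SLC17A3 their sunitinib call without sunitinib-resistant replicate 3.

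**Figure D2:**
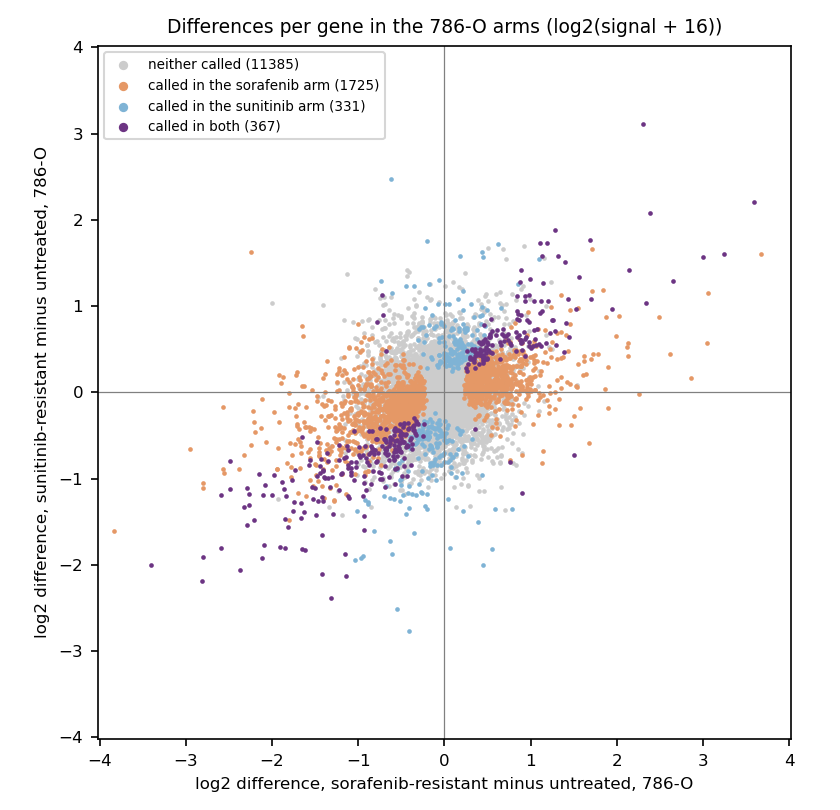
Each point is 1 gene, with its log2 difference in the 786-O sorafenib arm on the horizontal axis and in the sunitinib arm on the vertical axis, both resistant minus untreated on the log2(signal + 16) scale. Colours mark the 367 genes called in both arms, 1725 called in the sorafenib arm alone, 331 in the sunitinib arm alone and 11385 in neither; r = 0.41 across all genes.

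**Figure D3:**
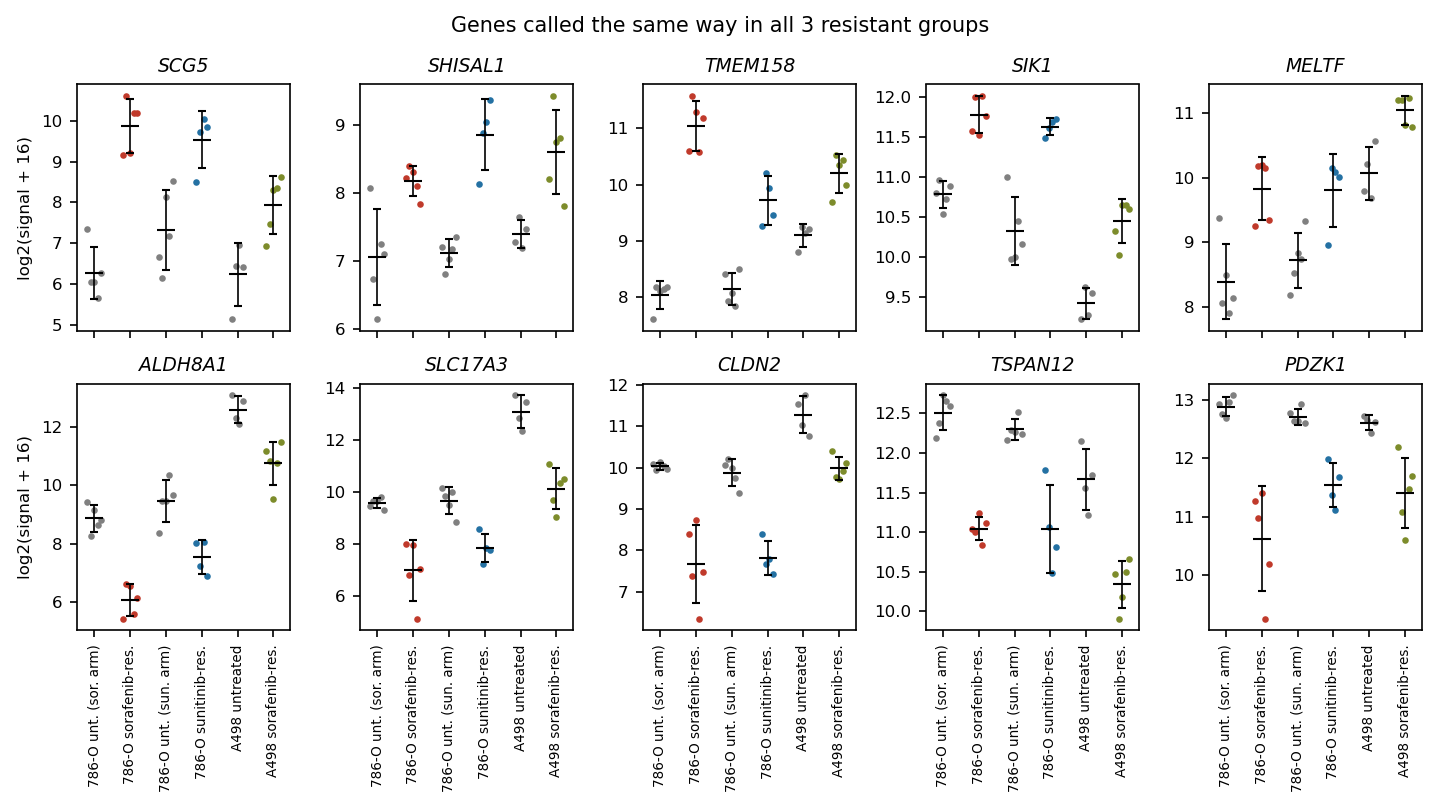
Levels of genes called in the same direction in all 3 comparisons, as log2(signal + 16) on the vertical axis, for untreated (grey) and resistant tumours of each arm. Each point is 1 array and bars are the mean ± SD; TMEM158 rose by 3.00, 1.57 and 1.10 and SLC17A3 changed by -2.59, -1.81 and -2.97 in the 3 arms.

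Averaged over both drugs in 786-O, SCD (2.42 ± 0.25), TMEM158 (2.29 ± 0.15) and DHRS3 (2.23 ± 0.23) rose most among genes without overlap in either arm, and ACSM2A (-2.72 ± 0.34), UGT2B4 (-2.71 ± 0.25) and LRRC31 (-2.50 ± 0.25) fell most. Other rises were in the complement protease C1R (1.46), the prostaglandin synthase PTGES (1.45), the bradykinin receptor BDKRB2 (1.44), the ectonucleotidase NT5E (1.35), EGFL6 (1.46), SLC9A9 (1.40) and LHFPL2 (1.25). Further falls were in ALDH8A1 (-2.35), CLDN2 (-2.21), SLC17A3 (-2.20), SHANK3 (-2.02), UGT3A1 (-1.93), AKR1C3 (-1.92) and CALCRL (-1.89). The average called 1040 rises and 1453 falls, 246 of them by at least 1 on the log2 scale, and 4209 genes had an unadjusted p under 0.05. With arrays centred on the median there were 2479 calls with 50.5% of them higher, in place of 41.7%, so the excess of falls depends on the scaling.

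Of the 30 lists 15 passed in the average, and MAPK output, hypoxia, stress response and matrix proteases held with an estimated correlation. MAPK output had 13 higher and 1 lower of 21 (14 and 1 adjusted over the list alone, mean 0.52, adjusted p = 3.18e-09, and adjusted p = 0.00936 with an estimated correlation). Hypoxia genes had 14 higher and 1 lower of 28 (15 and 1 adjusted over the list alone, mean 0.33, adjusted p = 7.34e-09, and adjusted p = 0.00936 with an estimated correlation). The stress response had 13 higher and 1 lower of 30 (14 and 1 adjusted over the list alone, mean 0.22, adjusted p = 2.81e-06, and adjusted p = 0.0116 with an estimated correlation). Matrix proteases had 9 higher and 2 lower of 18 (10 and 3 adjusted over the list alone, mean 0.32, adjusted p = 0.00115, and adjusted p = 0.0304 with an estimated correlation). Angiogenic growth factors and chemokines passed in the average and not in either arm, with 5 rises and 2 falls in 27 (6 and 2 adjusted over the list alone; mean 0.14, adjusted p = 0.0301, and adjusted p = 0.209 with an estimated correlation), and with ANGPTL4 (1.97 ± 0.24), CCN2 (1.36 ± 0.26) and ADM (0.60 ± 0.08). That list lost its call without sunitinib-arm untreated replicate 5 or sunitinib-resistant replicate 2, up to an adjusted p of 0.0642, and with arrays centred on the median.

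Of the other lists that passed in the average, 7 shifted upward and 3 downward. Interferon genes had 21 higher and 0 lower of 38 (28 and 0 adjusted over the list alone, mean 0.48, adjusted p = 9.65e-16, and adjusted p = 0.0636 with an estimated correlation). Cholesterol synthesis had 7 higher and 0 lower of 16 (9 and 0 adjusted over the list alone, mean 0.32, adjusted p = 2.51e-05, and adjusted p = 0.176 with an estimated correlation). Mesenchymal genes had 6 higher and 1 lower of 21 (8 and 1 adjusted over the list alone, mean 0.29, adjusted p = 1.35e-04, and adjusted p = 0.110 with an estimated correlation). MHC class I had 7 higher and 0 lower of 18 (8 and 0 adjusted over the list alone, mean 0.19, adjusted p = 1.35e-04, and adjusted p = 0.162 with an estimated correlation). Glycolysis had 5 higher and 0 lower of 18 (5 and 0 adjusted over the list alone, mean 0.21, adjusted p = 8.24e-04, and adjusted p = 0.162 with an estimated correlation). Fatty acid genes had 8 higher and 2 lower of 17 (8 and 2 adjusted over the list alone, mean 0.24, adjusted p = 0.00203, and adjusted p = 0.0921 with an estimated correlation). Immediate early genes had 7 higher and 0 lower of 16 (7 and 0 adjusted over the list alone, mean 0.26, adjusted p = 0.00492, and adjusted p = 0.162 with an estimated correlation). NRF2 targets had 2 higher and 8 lower of 20 (2 and 9 adjusted over the list alone, mean -0.40, adjusted p = 0.00203, and adjusted p = 0.152 with an estimated correlation). The fibroblast list had 1 higher and 6 lower of 16 (1 and 7 adjusted over the list alone, mean -0.49, adjusted p = 0.00293, and adjusted p = 0.162 with an estimated correlation). Drug transporters had 1 higher and 8 lower of 19 (2 and 8 adjusted over the list alone, mean -0.28, adjusted p = 0.0349, and adjusted p = 0.203 with an estimated correlation). The drug transporter list lost its call without sorafenib-resistant replicate 5 or sunitinib-arm untreated replicate 4, up to an adjusted p of 0.0620. Named members included RSAD2 (1.13), IFITM1 (1.12), MX2 (1.08), INSIG1 (1.08), FOS (1.08) and ATF3 (0.69), and FAP (0.72) and FOS lost their call without any of several single arrays, up to an adjusted p of 0.107.

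The difference between the drugs in 786-O was tested as the sorafenib difference minus the sunitinib difference. MAPK output genes stood higher on the sorafenib side, with 7 of 21 genes past the threshold and 0 below (12 and 1 adjusted over the list alone; mean 0.72, adjusted p = 1.02e-10, and adjusted p = 0.00737 with an estimated correlation). The ERK phosphatase DUSP6 (1.72 ± 0.24), the EGF family ligand EREG (1.95 ± 0.45) and PHLDA1 (1.60 ± 0.29) were among them. Single genes higher on that side were MFSD2A (2.70 ± 0.54), SLCO4A1 (2.48 ± 0.35), CIDEB (2.26 ± 0.51), A4GALT (2.24 ± 0.29) and HMGA1 (2.17 ± 0.50). A4GALT was already called lower in untreated tumours of the sorafenib arm than of the sunitinib arm, which makes up a part of its difference. The lowest were WFDC21P (-3.10 ± 0.48), SPTB (-2.42 ± 0.47), TSPAN2 (-2.40 ± 0.34), COL1A1 (-2.29 ± 0.50) and MAP1LC3C (-2.01 ± 0.44). In all 61 genes were higher and 70 lower, 77 of them by at least 1 on the log2 scale, and 1987 genes had an unadjusted p under 0.05.

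Of the 10 lists that passed, the MAPK list alone held with an estimated correlation. Cholesterol synthesis had 0 higher and 0 lower of 16 (9 and 0 adjusted over the list alone, mean 0.52, adjusted p = 1.59e-07, and adjusted p = 0.183 with an estimated correlation). The fibroblast list had 0 higher and 1 lower of 16 (0 and 1 adjusted over the list alone, mean -0.80, adjusted p = 3.51e-05, and adjusted p = 0.164 with an estimated correlation). Skeletal muscle had 0 higher and 0 lower of 6 (0 and 4 adjusted over the list alone, mean -1.52, adjusted p = 3.88e-04, and adjusted p = 0.170 with an estimated correlation). Oxidative phosphorylation had 0 higher and 0 lower of 25 (0 and 0 adjusted over the list alone, mean -0.18, adjusted p = 0.00119, and adjusted p = 0.608 with an estimated correlation). MHC class I had 0 higher and 0 lower of 18 (2 and 0 adjusted over the list alone, mean 0.18, adjusted p = 0.00783, and adjusted p = 0.550 with an estimated correlation). Ribosomal proteins had 0 higher and 0 lower of 20 (0 and 0 adjusted over the list alone, mean -0.20, adjusted p = 0.00783, and adjusted p = 0.795 with an estimated correlation). Extracellular matrix had 0 higher and 2 lower of 28 (0 and 2 adjusted over the list alone, mean -0.36, adjusted p = 0.0181, and adjusted p = 0.550 with an estimated correlation). Interferon genes had 0 higher and 0 lower of 38 (0 and 0 adjusted over the list alone, mean 0.15, adjusted p = 0.0186, and adjusted p = 0.780 with an estimated correlation). Matrix proteases had 0 higher and 0 lower of 18 (3 and 1 adjusted over the list alone, mean 0.26, adjusted p = 0.0187, and adjusted p = 0.170 with an estimated correlation). The fibroblast list was 0.36 higher in the untreated tumours of the sorafenib arm than in those of the sunitinib arm, and -0.44 apart in the resistant tumours. Muscle markers were 0.61 and -0.91 apart. The doses differed, and the arms also differ in the first number of the sample titles, so drug and tumour series cannot be told apart here. The count of 131 was 79 without sorafenib-arm untreated replicate 2, 74 without its replicate 4, 79 and 67 without sorafenib-resistant replicates 4 and 5, 69 without sunitinib-arm untreated replicate 5, and 65 and 64 without sunitinib-resistant replicates 1 and 4. HMGA1, EREG, CIDEB, COL1A1 and MAP1LC3C lost their call without at least 1 array, all 5 without sunitinib-arm untreated replicate 5, up to an adjusted p of 0.0810. The MHC class I, matrix, interferon, protease and ribosomal lists lost theirs, up to an adjusted p of 0.483. Means moved by over 1.5 times for ribosomal proteins (-0.08 without sorafenib-arm untreated replicate 5, and -0.13, -0.11 and -0.32 without sunitinib-resistant replicates 1, 3 and 4) and MHC class I (0.11 without sorafenib-resistant replicate 4). For interferon genes the mean was 0.08 without sorafenib-arm untreated replicate 1, 0.24 and 0.01 without sorafenib-resistant replicates 2 and 4, and 0.07 without sunitinib-resistant replicate 3. Without the 2 arrays of high ACTB difference the count was 51, and without the filter on dim genes 73.

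The response of A498 to sorafenib was set against that of 786-O as the A498 difference minus the 786-O difference. The first number of the sample titles differs between these lines as well, so line and tumour series cannot be told apart here. Interferon-stimulated genes were lower on the A498 side (mean -0.61, adjusted p = 4.92e-15, and adjusted p = 0.0897 with an estimated correlation). ISG20 (-1.62 ± 0.27), USP18 (-1.23 ± 0.30) and OAS1 (-1.18 ± 0.22) were among them. Fibroblast and pericyte markers were higher there (mean 1.17, adjusted p = 3.81e-06, and adjusted p = 0.0597 with an estimated correlation). The collagens COL3A1 (2.72 ± 0.44), COL1A2 (2.31 ± 0.40) and COL1A1 (2.31 ± 0.50) were among them. Another probe set of COL3A1 was significant in the opposite direction. The single genes furthest apart were UGT2B4 (3.96 ± 0.51), AIF1 (3.34 ± 0.97), IGFBP2 (3.16 ± 0.77), CCL5 (3.14 ± 0.75) and THBS4 (2.92 ± 0.56) on the A498 side. On the 786-O side they were MMP1 (-3.95 ± 0.71), GLDC (-3.76 ± 0.94), MFSD2A (-3.65 ± 0.54), CRYBB3 (-3.15 ± 0.33) and SLC2A2 (-3.07 ± 0.73). In all 417 genes were higher and 299 lower, 311 of them by at least 1 on the log2 scale, and 2847 genes had an unadjusted p under 0.05.

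Of the 12 lists that passed, 0 held with an estimated correlation. Interferon genes had 0 higher and 9 lower of 38 (0 and 19 adjusted over the list alone, mean -0.61, adjusted p = 4.92e-15, and adjusted p = 0.0897 with an estimated correlation). The fibroblast list had 5 higher and 0 lower of 16 (8 and 0 adjusted over the list alone, mean 1.17, adjusted p = 3.81e-06, and adjusted p = 0.0597 with an estimated correlation). Cholesterol synthesis had 0 higher and 1 lower of 16 (0 and 1 adjusted over the list alone, mean -0.53, adjusted p = 8.87e-07, and adjusted p = 0.118 with an estimated correlation). MHC class I had 0 higher and 3 lower of 18 (0 and 4 adjusted over the list alone, mean -0.31, adjusted p = 1.65e-05, and adjusted p = 0.118 with an estimated correlation). Extracellular matrix had 7 higher and 1 lower of 28 (12 and 2 adjusted over the list alone, mean 0.64, adjusted p = 1.19e-04, and adjusted p = 0.118 with an estimated correlation). Ribosomal proteins had 0 higher and 0 lower of 20 (0 and 0 adjusted over the list alone, mean 0.32, adjusted p = 5.84e-04, and adjusted p = 0.611 with an estimated correlation). Immediate early genes had 0 higher and 1 lower of 16 (0 and 3 adjusted over the list alone, mean -0.41, adjusted p = 0.00142, and adjusted p = 0.118 with an estimated correlation). The p53 list had 1 higher and 0 lower of 22 (1 and 0 adjusted over the list alone, mean 0.31, adjusted p = 0.00566, and adjusted p = 0.217 with an estimated correlation).

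Matrix proteases had 0 higher and 4 lower of 18 (0 and 5 adjusted over the list alone, mean -0.43, adjusted p = 9.70e-04, and adjusted p = 0.0597 with an estimated correlation). MAPK output had 2 higher and 6 lower of 21 (2 and 11 adjusted over the list alone, mean -0.52, adjusted p = 4.19e-06, and adjusted p = 0.0597 with an estimated correlation). Hypoxia genes had 0 higher and 5 lower of 28 (0 and 6 adjusted over the list alone, mean -0.28, adjusted p = 5.22e-04, and adjusted p = 0.0989 with an estimated correlation). NRF2 targets had 6 higher and 0 lower of 20 (7 and 0 adjusted over the list alone, mean 0.56, adjusted p = 1.81e-04, and adjusted p = 0.0897 with an estimated correlation). The hypoxia genes included ANGPTL4 (-2.27 ± 0.48), BHLHE40 (-0.95 ± 0.23) and SLC2A1 (-0.67 ± 0.17), and the MAPK genes DUSP5 (-1.42 ± 0.30) and FOSL1 (-1.09 ± 0.29). Among NRF2 targets AKR1C3 (2.26 ± 0.37) and AKR1C2 (1.65 ± 0.30) were higher, and AKR1C1 (1.43 ± 0.25) came out at -0.40 without the probe sets open to cross-hybridisation. AIF1 lost its call without any of several single arrays, and SESN1 (0.83), TAPBP (-0.52), SLC2A1 and FOSL1 lost theirs without at least 1, up to an adjusted p of 0.106. Without the 2 arrays of high ACTB difference the count was 458 in place of 716. The ribosomal mean of 0.32 was 0.20 without 786-O untreated replicate 5 and 0.21 without A498 untreated replicate 3, and called in both. Centring on the median gave 694 calls with 52.9% higher in place of 58.2%.

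Untreated A498 tumours differed from untreated 786-O tumours of the sunitinib arm in 8002 genes, 3772 higher and 4230 lower, 3099 of them by at least 1 on the log2 scale, with 8551 at an unadjusted p under 0.05. FGB, a fibrinogen chain, had a mean signal of 28.6 ± 23.6 in 786-O and 13842 ± 4955 in A498 (SD, n = 5 and 4), GPX3, the secreted glutathione peroxidase, of 58.2 ± 21.9 and 16913 ± 6495, and the sodium channel subunit SCNN1G of 10.8 ± 10.0 and 6395 ± 1429. Others higher in A498 were SULF2 (8.10), GDA (7.75), TSPAN8 (7.73), BBOX1 (7.47), CLRN3 (7.40), DSP (7.39) and ANPEP (7.38). Lower in A498 were PDE10A (-7.22), RARRES2 (-7.03), ZNF655 (-6.80), RNASE1 (-6.77), SCRN1 (-6.73), GSTT1 (-6.38), RAC2 (-6.18), APCDD1L-DT (-6.14) and ZNF83 (-5.96). Except for RARRES2 each of these lay below the filter limit in A498, as the rises did in 786-O. Of 20 oxidative stress and NRF2 target genes 17 were higher and 1 lower (17 and 1 adjusted over the list alone; mean 1.98, adjusted p = 1.38e-08, and adjusted p = 0.0172 with an estimated correlation). AKR1B10 (6.76 ± 0.23), ABCC2 (5.90 ± 0.25) and AKR1C2 (4.66 ± 0.22) were among them. The other 29 lists had an adjusted p from 0.109 up.

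The untreated 786-O tumours of the sorafenib and sunitinib arms differ by label only in the arm and in the first number of the titles. Their mean ACTB 3-prime minus 5-prime differences were 0.455 ± 0.328 and 0.226 ± 0.118 (SD, exact permutation p = 0.127), and with ACTB as a covariate, added after the data were seen, 24 genes were called in place of the 38 here. In the sorafenib arm 29 genes were higher and 9 lower, 17 of them by at least 1 on the log2 scale, with 1819 at an unadjusted p under 0.05, and groups did not overlap in 2.77% of genes where chance gives 0.794%. The genes furthest apart were LURAP1 (1.73), MYF6 (1.63), SYN2 (1.48), WFDC9 (1.43) and PKP2 (1.35), which were higher, and CCR10 (-1.42), A4GALT (-1.14), MST1 (-0.99) and ZNF865 (-0.98), which were lower. PRUNE2 was lower too, with mean signals of 463 and 223 in the sunitinib and sorafenib arms. The 10 genes had adjusted p-values from 0.00631 (PRUNE2) to 0.0491 (MYF6). Of these only PRUNE2 and MST1 lay above the filter limit in both groups. Of the lists 6 passed, and 0 held with an estimated correlation. Cell cycle genes had 0 higher and 0 lower of 38 (0 and 0 adjusted over the list alone, mean 0.21, adjusted p = 2.16e-05, and adjusted p = 0.683 with an estimated correlation). Interferon genes had 0 higher and 0 lower of 38 (2 and 0 adjusted over the list alone, mean 0.19, adjusted p = 0.0158, and adjusted p = 0.703 with an estimated correlation). The fibroblast list had 0 higher and 0 lower of 16 (2 and 0 adjusted over the list alone, mean 0.36, adjusted p = 0.0158, and adjusted p = 0.683 with an estimated correlation). Muscle markers had 0 higher and 0 lower of 6 (2 and 0 adjusted over the list alone, mean 0.61, adjusted p = 0.0355, and adjusted p = 0.683 with an estimated correlation). The stress response had 0 higher and 0 lower of 30 (0 and 0 adjusted over the list alone, mean -0.15, adjusted p = 0.00335, and adjusted p = 0.385 with an estimated correlation). Lysosome genes had 0 higher and 0 lower of 26 (0 and 0 adjusted over the list alone, mean -0.09, adjusted p = 0.00399, and adjusted p = 0.505 with an estimated correlation). The count of 38 was 16, 24, 16 and 22 without sorafenib-arm replicates 2, 3, 4 and 5, and 23, 14 and 23 without sunitinib-arm replicates 2, 3 and 5. Centring on the median gave 32 calls with 65.6% higher in place of 76.3%, and with only these 10 arrays in the fit limma called 0, while 1765 genes had an unadjusted p under 0.05. Of the 10 genes named 7 lost their call without at least 1 array, up to an adjusted p of 0.131.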

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

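The tests of macrophage RNA against interferon genes, of the largest part the ACTB difference can make up and of the share of host RNA were set after the results were seen. A single array stood far from the others of its group, by the gap to the nearest as a share of the group's range, in 6 of 66 list means, 3 of 120 gene levels and 2 of 18 array measures, where chance gives about 1 in 20. For the ACTB 3-prime minus 5-prime difference these were 786-O untreated replicate 5 of the sorafenib arm (0.780) and sunitinib-resistant replicate 3 (0.860). For list means they were interferon genes in 786-O untreated replicate 1 of the sorafenib arm (0.725), the stress response in sunitinib-resistant replicate 1 (0.837) and muscle markers in sunitinib-resistant replicate 2 (0.932). In A498 they were MAPK output (0.893) and ribosomal proteins (0.915) in untreated replicate 3 and drug transporters in sorafenib-resistant replicate 3 (0.765). For genes they were TMEM158 (0.880) and DEFB1 (0.830) in 786-O untreated replicate 1 of the sorafenib arm, and UGT2B4 (0.723) in sorafenib-resistant replicate 4.

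The 2 drug arms of 786-O differed, by the test of the difference itself, in 131 genes, where drug, dose and tumour series cannot be told apart. Sorafenib minus sunitinib was highest for MFSD2A (2.70), SLCO4A1 (2.48), CIDEB (2.26), A4GALT (2.24) and HMGA1 (2.17) and lowest for WFDC21P (-3.10), SPTB (-2.42), TSPAN2 (-2.40), COL1A1 (-2.29) and MAP1LC3C (-2.01). A part of the A4GALT value lies in the untreated tumours, where the gene was called lower in the sorafenib arm. Lists that differed were MAPK output (0.72), cholesterol synthesis (0.52), matrix proteases (0.26), MHC class I (0.18), interferon genes (0.15), oxidative phosphorylation (-0.18), ribosomal proteins (-0.20), extracellular matrix (-0.36), fibroblast and pericyte (-0.80) and skeletal muscle (-1.52), of which MAPK output alone held with an estimated correlation. The interferon difference was 0.01 without sorafenib-resistant replicate 4 and 0.05 without the 2 arrays of highest ACTB difference, and was called in neither. The sorafenib arms of the 2 lines differed in 716 genes, where line and tumour series cannot be told apart. A498 minus 786-O was highest for UGT2B4 (3.96), AIF1 (3.34), IGFBP2 (3.16), CCL5 (3.14) and THBS4 (2.92) and lowest for MMP1 (-3.95), GLDC (-3.76), MFSD2A (-3.65), CRYBB3 (-3.15) and SLC2A2 (-3.07). The lists were fibroblast and pericyte (1.17), extracellular matrix (0.64), NRF2 targets (0.56), ribosomal proteins (0.32), p53 targets (0.31), hypoxia (-0.28), MHC class I (-0.31), immediate early genes (-0.41), matrix proteases (-0.43), MAPK output (-0.52), cholesterol synthesis (-0.53) and interferon genes (-0.61), and 0 of the 12 held with an estimated correlation (camera adjusted p from 0.0597 to 0.611).

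Probe sets without a single gene symbol, which the comparisons leave out, also held differences: of 6290 tested, 330 passed in 786-O with sorafenib, 112 in 786-O with sunitinib and 99 in A498.

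Other splits of the same arrays were fitted 100 times for each result, the real one included. The smallest share that 100 splits can give is 1 in 100, and shares were not adjusted over the results. The real split alone gave as many genes for 786-O with sorafenib (2092, and 67 in the highest other) and 786-O with sunitinib (698 and 293). It did so too for A498 (875 and 369) and for the average (2493 and 7), which argues against chance at that level. The real split was also highest for the difference between the lines (716 and 614), untreated A498 against 786-O (8002 and 6414) and the untreated 786-O arms (38 and 9). Between the lines the splits permuted state within each line, so they test no effect of state in either line, not equal responses. For the untreated 786-O arms limma called 0 genes with only their 10 arrays in the fit, so chance is not excluded there. For the difference between the drugs 3 splits, the real one included, gave at least the real 131, the highest 254. At 3 in 100, not adjusted over the results, and with another split above the real one, chance is not excluded. For the agreement of contrasts 1 split, the real one, gave r as high for 786-O with both drugs (0.41, and 0.32 in the highest other), for both lines under sorafenib (0.22 and 0.19) and for 786-O with sunitinib against A498 (0.15 and 0.13).

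Interferon-stimulated genes were higher in both 786-O resistant groups (list means 0.56 and 0.41), where camera with an estimated correlation gave an adjusted p of 0.0627 and 0.261. An exact permutation of the arrays' list means gave two-sided p = 0.00794 in both arms, the smallest this design can give. Adjusted over 30 lists it was 0.0198 with sorafenib and 0.0595 with sunitinib. This argues against spread between tumours alone in the sorafenib arm, while in the sunitinib arm the adjusted value did not pass. The list was singled out for its rise in these same arrays. RNA quality stays open for a part of the rise, and for more where ACTB does not measure it. With the ACTB difference as a covariate the list kept at least 98.8% of its mean, but the groups differed in ACTB by less than its standard error (-0.004 ± 0.163 and 0.0108 ± 0.0638), so this could not move the mean. The slope of the list mean on the ACTB difference within all groups was 0.442 ± 0.210. The group difference times this slope, each taken without sign and widened by 2 standard errors, came to 51.2% and 29.2% of the list means. As far as ACTB measures RNA quality, this argues against it as the cause of the whole rise. A part stays open, since 51.2% lies over the 50% set as a bound. Both the 50% bound and the reading for the whole rise were set after the results were seen. More macrophage RNA was not seen in the macrophage markers, whose list means changed by -0.27 and -0.18 (exact permutation p = 0.0159 and p = 0.246). Macrophage minus interferon means changed by -0.82 and -0.59 (exact permutation p = 0.00794 and p = 0.0159). The markers lay near the filter limit in untreated tumours of both arms (medians 7.03 and 6.81 against 6.72), and 8 of the 21 listed lay below the filter. They measure macrophage RNA too weakly to settle this. CTSS, the brightest of them (10.5 and 10.4), changed by 0.38 and -0.04 and was called in neither arm. The drug, the size of the tumours and the time on study cannot be told apart, and none was tested as a biological explanation.

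Fibroblast and pericyte genes were lower in 786-O sorafenib-resistant tumours (mean -0.90). In A498 the list did not pass camera (mean 0.27), while an exact permutation of array means gave p = 0.0317 (0.159 adjusted over 30 lists). Permuting state within each line gave exact p = 0.000126 over 31752 arrangements for the difference of 1.17 between the lines. This argues against spread between tumours with no effect of state in either line. It does not test whether the lines respond alike, and the pattern was picked from these data. A lower share of all host RNA in these 786-O tumours may account for the fall of the fibroblast list. The fibroblast list changed by -0.63 more than the mean of the endothelium and macrophage lists (exact permutation p = 0.00794), but those lists started from median levels of 7.25 and 7.03, near the limit of 6.72, so a fall of all host RNA is not excluded. Their means changed by -0.26 and -0.27 (exact p = 0.0238 and p = 0.0159), with camera adjusted p = 0.699 and 0.970, and 4 of 7 endothelium and 4 of 11 macrophage genes went up. A further 13 endothelium and 8 macrophage markers lay below the filter. Skeletal muscle markers (6 genes), which can also come from the host, changed by -0.81 (exact permutation p = 0.0238) from a median level of 7.38. COL3A1, the brightest member of the fibroblast list, had a level of 12.2 in untreated tumours of the sorafenib arm. The effects of drug, tumour size and time cannot be told apart.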

How the results depend on the processing

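The ACTB covariate, the set without the 2 arrays of highest ACTB difference and the permutation of list means were added after the data were seen. With 4 or 5 arrays per group counts moved with single arrays, and dim genes near the background limit the size of changes. Over all named genes and settings 8451 values kept direction and side of the threshold, 560 lost their call, 1 gained it and 3 reversed, and of list results 1235 kept both and 131 lost their call; the cause was not tested except where fewer arrays or a stricter rule lower a count. Reversed were HK2 in 786-O with sorafenib as the mean of its probe sets (-0.085), AKR1C1 between the lines without probe sets open to cross-hybridisation (-0.40) and TMT1A with sunitinib at a pseudocount of 1 (1.26), each through another use of a gene's probe sets.

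A threshold of 1 on the log2 scale left 448 (786-O sorafenib), 155 (786-O sunitinib), 160 (A498), 246 (average), 77 (between drugs), 311 (between lines), 3099 (untreated lines) and 17 genes (untreated 786-O arms). The difference between drugs gave 73 genes without the filter. The untreated 786-O arms gave 20 without the filter, 17 with the stricter filter, 91 with array weights, 24 with the ACTB covariate and 24 at a pseudocount of 1. Array weights gave 1316 in A498. With only the arrays of a comparison there were 259 (786-O sunitinib), 185 (A498) and 0 by limma (untreated 786-O arms, where 1765 genes had an unadjusted p under 0.05). Pooled untreated 786-O tumours gave 1326 with sunitinib. Without the 2 ACTB arrays there were 1233 (786-O sorafenib), 51 (between drugs), 458 (between lines) and 24 (untreated 786-O arms). Without the filter r was 0.29 (both drugs), 0.16 (both lines) and 0.10 (sunitinib against A498), and 0.62, 0.33 and 0.25 over genes called in either.

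Lists called with an estimated correlation were 4 (786-O sorafenib), 2 (786-O sunitinib) and 0 (A498), and 4 in A498 with fry. Permuting list means over arrays, the smallest exact p was 0.00794 in each arm (adjusted over 30 lists 0.0198, 0.0595 and 0.159). Leaving out each array gave 1579 to 1931 genes (786-O sorafenib), 313 to 659 (786-O sunitinib, lowest without resistant replicate 3), 467 to 1020 (A498, without untreated replicate 1 and resistant replicate 1), 2012 to 2536 (average), 64 to 171 (between drugs, without sunitinib-resistant replicate 4 and sorafenib-resistant replicate 2), 506 to 746 (between lines), 7566 to 7817 (untreated lines) and 14 to 50 (untreated 786-O arms, without sunitinib-arm replicates 3 and 1). Also beyond 1.5 times were 442 and 396 with sunitinib (without untreated replicate 1 or resistant replicate 4) and 583 and 571 in A498 (without untreated replicate 4 or resistant replicate 3). Lists called ranged over 14 to 18, 7 to 12 and 5 to 8 (lowest without A498 resistant replicate 3), and r over 0.35 to 0.45, 0.20 to 0.23 and 0.14 to 0.17.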

Other observations

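Other genes were called in the same direction in all 3 arms, with values for 786-O with sorafenib, 786-O with sunitinib and A498 in that order. Arginase 2 (ARG2) rose by 2.34, 1.04 and 0.96, the AP-1 member FOSL1 by 1.95, 0.97 and 0.85, the creatine transporter SLC6A8 by 0.85, 0.85 and 0.70, stanniocalcin 1 (STC1) by 1.44, 0.64 and 0.59, the integrin subunit ITGB5 by 1.06, 0.55 and 0.67 and PMEPA1, a TGF-beta target, by 0.53, 0.68 and 0.65. The kidney Na,K-ATPase subunit FXYD2 changed by -1.14, -2.13 and -1.48, the phosphate transporter SLC17A1 by -1.88, -1.03 and -1.36, the efflux pump ABCB1 by -0.91, -0.76 and -1.49, the soluble guanylate cyclase subunit GUCY1A1 by -1.05, -1.02 and -0.92, and TLR3, a receptor of double-stranded RNA, by -0.92, -0.62 and -0.72. These were picked after their values were seen.

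Kidney tubule transport genes were among the genes lower in all 3 resistant groups, and a list of 72 proximal tubule genes was then written, of which 47 were measured. Of these 15 were called lower in 786-O with sorafenib, 11 in 786-O with sunitinib and 11 in A498, and 2, 0 and 0 higher. GATM, the first enzyme of creatine synthesis, changed by -1.81, -1.57 and -0.59, of which the A498 value did not pass. A hypothesis is that resistant tumours lose proximal tubule genes as a class. It was tested on the 37 members that no rule had named, whose means were -0.41, -0.28 and -0.52. By camera with an estimated correlation they were lower in 1 of 3 contrasts, A498 (p = 0.0211, 3 of 37 called), while 786-O gave p = 0.287 and p = 0.249. At the preset correlation p was 0.0216, 0.0126 and 1.72e-07, and an exact permutation of array means gave 0.00794, 0.0238 and 0.0317, so the tests disagree in 786-O and the hypothesis stays open. A lower share of human tumour RNA would lower tumour genes alike, and in 786-O the cell cycle genes did not fall (medians 0.002 and 0.03). The gap between them and the tubule genes not named before lay within 2 standard errors there, so the test did not settle it in 786-O. In A498 a lower share of tumour RNA was argued against only with bootstrap standard errors over genes. Resampling took genes, not tumours, as independent, though the estimated correlation was 0.152 for the 47 genes and 0.140 for the 37. The median of the 47 genes minus that of 38 cell cycle genes was -0.42 ± 0.21, -0.26 ± 0.12 and -0.62 ± 0.14 (bootstrap standard errors), but 10 of the 47 had been named before the list was written. With the other 37, a test set after these results were seen, it was -0.23 ± 0.17, -0.15 ± 0.11 and -0.50 ± 0.10, past 2 standard errors in A498 alone.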
